A study of Danio rerio with 9 samples.

How the data were processed

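The samples were 9 pools of 2 zebrafish brains, 5 of control and 4 of methylmercury fish, grouped by the treatment given in the labels. Each was run on its own 2-colour array with the sample in Cy5 and a common reference in Cy3, and per the labels no array had its dyes exchanged. The arrays hold 22575 spots in 105 rows and 215 columns, of which 21495 are gene probes with 1 spot each. Per the file headers, the arrays were scanned and quantified by the authors with Agilent Feature Extraction 9.1.1.1, which gives the mean spot and local background intensity of each channel. Processed intensity values in the deposited files are, per the file headers, background-subtracted, spatially detrended and dye-normalized, and the deposited log10 ratio is that of processed Cy5 over processed Cy3. A deposited value table of the series holds 22575 values per array on the log10 scale. Set against each array's log10 ratios it differed by less than rounding, at most 0.005, so its direction is sample over reference, it is not centred beyond that, and each column has a median of 0. In that table, 29.8% to 40.9% of values per array are exactly 0. The labels name no statistical method.

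From the deposited intensity values, the background was corrected in both channels with normexp and an offset of 50, and log2 ratios of Cy5 over Cy3 were computed with loess normalization within each array, in R 4.3.3 with limma 3.58.1. The offset draws ratios of dim probes towards 0. Control spots were left out after normexp and had no weight in loess, and spots flagged as non-uniform in either channel, 0.344% of spots, were left out on their array. Probes well above background in Cy5 on at least 4 of the 9 arrays were tested, 9949 in all. The groups were compared with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over these probes and a threshold of 0.05. Among the named probes, hbba1 was saturated in Cy5 on 1 array and kept at its value. Every log2 difference is methylmercury minus control.

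Gene names came from the deposited files' own columns, updated by accession for 7323 probes, by symbol for 756 and by an older name for 2261 through gene tables of the GRCz12tu assembly, and kept as given for 11155. In all, 10060 probes carried a gene symbol. Named genes were chosen by a rule fixed before the data were examined, namely the 12 genes with the largest change in each direction among probes past the threshold with all methylmercury arrays on one side of the control mean, filled up by the smallest unadjusted p. To these were added a fixed set of mercury, hormone and brain genes, and the leading members of each gene list by p. Where several probes measured a gene, the one with the smallest p was named and the others are given beside it, except for the leading members of gene lists. A gene that this rule selects is not reported here and was left out of the search for outlying values. Genes named by any other route are said to be chosen after their values were seen.

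Gene lists, 36 in number, were written before the data were examined and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists that had at least 5 measured genes. Each gene was represented by its brightest probe with values on all arrays, since camera takes no missing values, so a gene can have another probe here than among the named genes. Beside camera, lists were tested with a correlation estimated per list, with fry, and by exact permutation of the list mean over the arrays. In the reference channel, lists were compared with 2000 random lists matched on brightness.

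Alternatives fixed before the data were examined varied the background correction, the offset, the normalization, the filter on dim probes, the flags, the variance model, the probe chosen for a gene, the threshold, the source of the values, a replicate block and each array left out in turn. Another 2 alternatives, the removal of a smooth position trend from each array and the omission of the arrays of control 1 and methylmercury 1, were chosen after seeing the data. A slide or scan batch was not fitted, because the headers give 9 slides for 9 arrays and 1 scan day.

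The scripts were tested on simulated data built on the 9949 probes of this comparison. Probes were raised and lowered in turn, and estimates are given in the direction of the shift. Of 100 probes shifted by 0.5 on the log2 scale, 15 were recovered, with a median estimate of 0.29. Of 100 shifted by 1.0, 75 were recovered, with a median estimate of 0.62. Among 9726 unchanged probes, 10 were called. The simulated noise was set from log2 ratios that the offset had already drawn towards 0, and the offset drew it in again. Noise of dim probes was therefore smaller than in the data. The many shifted probes also eased the adjusted threshold. The recovered shares can thus be too high and do not give the power of the real comparison. A list raised by 0.3 among 8059 genes was recovered with 0 false lists. The noise was drawn independently for each probe, so the simulated genes were not correlated. In the real data the correlation estimated for the ribosomal list was 0.36, so the simulation does not show how many false lists correlated genes give.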

Results

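Brains of adult female zebrafish of the wild-type AB-1 strain were profiled 96 h after an injection of methylmercury, an organic mercury compound that enters the brain and binds thiol groups. Treated fish received 0.5 µg of methylmercury per g of body weight and control fish received 0 µg per g in the same sodium carbonate vehicle. Each sample pooled 2 brains, and the labels give separate pooled samples, 5 of control and 4 of methylmercury fish. The RNA of each pool was hybridised in Cy5 to its own 2-colour oligonucleotide array, against a common reference in Cy3 that the labels describe as a brain RNA pool of both treatments. Of 21495 gene probes per array, between 40.7% and 53% were well above background in the sample channel and between 49.4% and 57.5% in the reference channel. Log2 ratios of sample over reference correlated at 0.93 to 0.98 between pairs of arrays, across probes, which are not independent replicates. The number of arrays limits the precision of every value below.

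The comparison of methylmercury with control asks which brain transcripts differ after a single acute dose. A single probe changed, as TC294381, a transcript with no gene symbol in the sources used here, rose in methylmercury brains, and no probe with a gene symbol passed the adjusted threshold. The named genes with the smallest p had higher values in methylmercury and were tp53bp2a, the zebrafish homologue of a p53-binding protein that promotes cell death, and gsta.1, an alpha-class glutathione S-transferase that couples glutathione to reactive compounds. As groups, mRNAs of mitochondrial oxidative phosphorylation and sterol biosynthesis lay higher and those of cytosolic ribosomal proteins and of pan-neuronal and synaptic genes lay lower, although the medians of these last groups turned positive under median centring. The group results passed a test that assumes a small fixed correlation between genes, and none passed once that correlation was estimated from the data. In that first test, other splits of the 9 arrays into 5 and 4 gave a median of 5 lists, against 4 in the real one.

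TC294381, measured by the probe A_15_P104890, was 1.00 higher on the log2 scale in methylmercury, a 2.00-fold level. It had a log2 ratio of -1.87 ± 0.10 (SD, n = 5) in control and -0.87 ± 0.15 (SD, n = 4) in methylmercury pools, and 4 of the 4 methylmercury pools lay above every control pool. The difference had a standard error of 0.09 and a limma adjusted p of 0.00545 over 9949 probes. It came from the sample channel, where the difference was 1.03, against 0.03 in the reference channel. The call was lost with the scanner software's processed signals (1.33, adjusted p = 0.148), with median centring (1.18, adjusted p = 0.176) and with a replicate block (1.00, adjusted p = 0.335), within a range of 0.000475 to 0.335 over 23 alternatives. Across all probes, 123 had an unadjusted limma p below 0.01, where chance gives 99, and 629 had one below 0.05, where chance gives 497. Of the 123, 65 had higher and 58 lower values in methylmercury, but with median centring 29 of 30 such probes were higher. The number changed at an adjusted threshold of 0.10 was also 1.

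Among the 4587 gene symbols tested, on 6030 probes, the number changed was 0 in limma, and the smallest adjusted p was 0.123, for tp53bp2a. Its log2 ratio was -2.14 ± 0.15 (SD, n = 5) in control and -1.09 ± 0.32 (SD, n = 4) in methylmercury pools, a difference of 1.05 with a standard error of 0.14, and 4 of 4 methylmercury pools lay above every control pool. The tp53bp2a probe passed in 3 of 23 alternatives, namely with a smaller background offset (adjusted p = 0.0477), with array quality weights (adjusted p = 0.0282) and, in an alternative added after the data were seen, after removal of a position trend on the arrays (adjusted p = 0.0114), and its adjusted p reached 0.688 in another. For gsta.1 the log2 ratio was -2.73 ± 0.33 (SD, n = 5) in control and -1.47 ± 0.39 (SD, n = 4) in methylmercury, a difference of 1.26 with a standard error of 0.21 and an adjusted p of 0.202. The same adjusted p of 0.202 was obtained for ndufb2, an accessory subunit of respiratory complex I, with a difference of 0.58 and 0.25 on its other probe. Each of the 3 probes for degs1, the desaturase that completes ceramide synthesis, had a higher value in methylmercury, with differences of 0.89, 0.65 and 0.25 and a smallest adjusted p of 0.298.

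The other genes with higher values, none past the threshold, were iars1, the isoleucyl-tRNA synthetase, at 1.07, uqcrq, a subunit of respiratory complex III, at 0.39, and cirbpb, a cold-inducible RNA-binding protein, at 0.69. The other 2 probes of cirbpb gave -0.02 and -0.23, while all 4 probes of uqcrq had a positive difference. A difference of 0.53 was measured for cnot4b, a ubiquitin ligase tied to mRNA decay, and 0.51 for park7, the oxidative stress sensor known as DJ-1, whose other probe gave 0.27. Smaller differences were measured for znf593 at 0.41, with 0.44 and 0.10 on its other probes, for lrpap1, a chaperone of lipoprotein receptors, at 0.33 and for wtap, part of the complex that methylates adenosine in mRNA, at 0.32, with 0.20 in the sample channel alone and -0.06 on its other probe. Adjusted p for these 8 genes lay between 0.488 and 0.595.

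**Figure D1:**
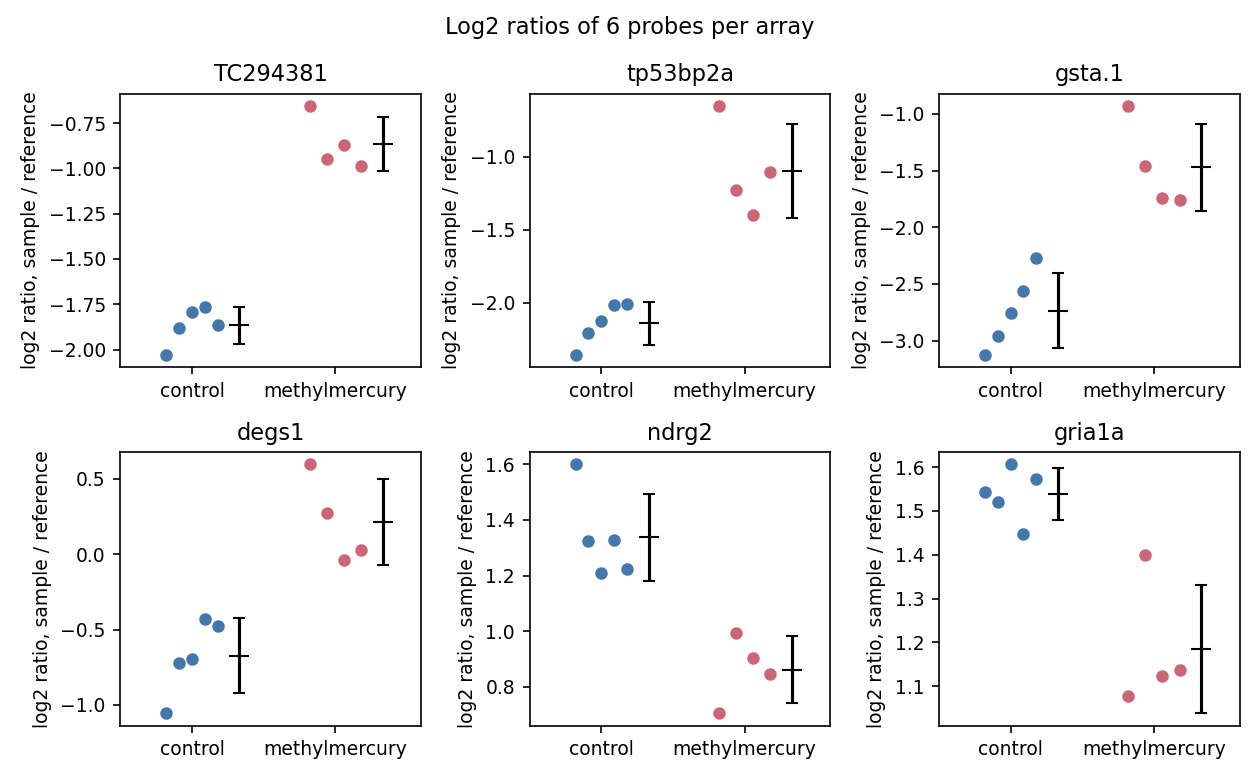
Log2 ratios of sample over reference for 6 probes in each of the 5 control (blue) and 4 methylmercury (red) pools, with the group mean and SD as a black bar. In each panel all 4 methylmercury pools lie on one side of every control pool, and only TC294381, with means of -1.87 and -0.87, passed the adjusted threshold.

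Lower values in methylmercury included those of ndrg2, an astroglia-enriched gene, at a log2 difference of -0.48 with a standard error of 0.10 and a limma adjusted p of 0.488, and its other probe gave -0.19. For kdm7aa, a histone demethylase, the difference was -1.05, with an adjusted p of 0.548. Leaving out the control 5 pool brought the adjusted p of kdm7aa to 0.0133, within a range of 0.0133 to 1.00 over 23 alternatives. A difference of -0.50 was measured for ncaldb, a calcium sensor of the neurocalcin family, and -0.35 for gria1a, an AMPA-type glutamate receptor subunit. The ribosomal protein gene rpl7 had -0.69, and all 4 of its other probes had negative differences between -0.14 and -0.38, but in the sample channel alone the difference of rpl7 was -0.36. The remaining genes were rassf8b at -0.56, ap3d1, a subunit of a vesicle coat adaptor, at -0.53, prr15la at -0.39, with -0.14 on its other probe, nudt3b, an inositol pyrophosphate phosphatase, at -0.35, rbmx, a splicing factor, at -0.33, and skib, a corepressor of TGF-beta signalling, at -0.27, with -0.11 on its other probe. Of the other 3 probes of rbmx, 1 had the same sign.

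Genes chosen in advance for what is known of mercury and of the brain did not pass the threshold in limma. For mt2, a metallothionein that binds metals, the 3 probes gave -0.44, 0.12 and 0.07, and without methylmercury 3 the -0.44 was -0.14. The spot of methylmercury 1 was left out for that probe, so the -0.14 rests on methylmercury 2 and methylmercury 4. The log2 difference was 0.11 for gclc, which catalyses the first step of glutathione synthesis, -0.12 for gstp1.2, with 0.04 and 0.20 on its other probes, and -0.04 for the thioredoxin reductase txnrd3. For the pituitary prohormone gene pomca it was 0.05, for the glial filament gene gfap 0.20, 0.10 and 0.16 on its 3 probes and for the myelin gene mbp -0.10, which was -0.46 without methylmercury 3. The mbp probe was well above background on 2 of the 4 methylmercury arrays. Tubulin genes gave 0.33 for tuba1b, with -0.30 and 0.08 on its other probes, and 0.26 for tubb5, with -0.03 and 0.22 on its other probes. The brain aromatase gene cyp19a1b had a difference of 0.83 with a standard error of 0.71, since its control SD was 1.45 (n = 5), and without control 2 the difference was 0.26. Its spot of methylmercury 1 was left out, so the methylmercury mean has n = 3. The globin genes hbaa1 and hbba1 had differences of 0.52 and 0.32 with standard errors of 0.71 and 1.03, and without control 1 these turned to -0.15 and -0.60. The immediate early gene fosab had a difference of -0.60 with a standard error of 0.23 and an adjusted p of 0.759. With 1 array left out, 12 of 13 of these genes moved by over 1.5 times at least once, against 0 of the genes with the smallest p. The latter were chosen from these same arrays for large differences relative to their spread. Many of the former had small differences, where such a ratio is easily reached, so the contrast does not show which genes are more reliable. The hormone genes prl, cga and fshb were not well above background on any array, gnrh3 was so on at most 1 array and hsp70.3 on 2, so these were not tested. No probe was found under the names hsp70l, hmox1a, txn, gh1, lhb, mbpa or tuba1a.

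Of 36 gene lists fixed before the data were examined, 35 had at least 5 measured genes, and 4 passed an adjusted p of 0.05 in camera with its preset correlation, over 8059 genes. Cytosolic ribosomal protein mRNAs, which encode the translation machinery, had a median log2 difference of -0.18 over 56 genes, 44 of them negative (camera adjusted p = 2.27e-05), although with median centring the median turned to 0.14. The mean of the list was -1.18 ± 0.22 (SD, n = 5) in control and -1.35 ± 0.16 (SD, n = 4) in methylmercury pools. With an estimated correlation the ribosomal list had an adjusted p = 0.937. Its call was also lost with processed signals, where the median was -0.06 (adjusted p = 0.175), and with Cy5 alone, where it was -0.02 (adjusted p = 0.666). Without control 1 its median was -0.07, and it still passed. Its members with the smallest p were rpl7 at -0.69, rps27.2 at -0.58, rps27a at -0.42 and rpl4 at -0.39. Oxidative phosphorylation genes, which encode the mitochondrial respiratory chain and ATP synthase, had a median of 0.13 over 42 genes, 31 of them positive (camera adjusted p = 0.00386). With median centring this median was 0.31. With an estimated correlation the oxidative phosphorylation list also had an adjusted p = 0.937, and without methylmercury 4 it had 0.0514. Its leading members were ndufb2 at 0.58, atp5pf at 0.44 and ndufb10 at 0.26, with atp5l at -0.71 in the other direction.

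Pan-neuronal and synaptic genes, the common markers of neurons, had a median of -0.16 over 16 genes, 12 of them negative (camera adjusted p = 0.0260), with a median of 0.03 under median centring. With an estimated correlation the neuronal list had an adjusted p = 0.937. Its call was also lost without control 1, where the median was -0.08 (adjusted p = 0.231), without methylmercury 4, where it was -0.07 (adjusted p = 0.0905), and without control 2, methylmercury 2 or methylmercury 3. Processed signals (adjusted p = 0.230) and Cy5 alone (adjusted p = 0.264) ended it too. The smallest p were those of elavl4, a neuronal RNA-binding protein, at -0.40, the synaptic vesicle genes sypb at -0.37 and syt1a at -0.37, and syn2a, a synapsin, at -0.29. Sterol biosynthesis genes, the cholesterol synthesis pathway, had a median of 0.14 over 10 genes, 9 of them positive (camera adjusted p = 0.0301), led by hmgcs1 at 0.38, ebp at 0.35 and msmo1 at 0.30. With an estimated correlation the sterol list had an adjusted p = 0.937. Its call was lost without any single one of control 2, control 3, control 4, methylmercury 1, methylmercury 3 and methylmercury 4, with adjusted p up to 0.237. It was also lost with processed signals (adjusted p = 0.166), although the median was 0.26 there. By exact two-sided permutation of the list means over the 9 arrays, p was 0.238 for the ribosomal, 0.0794 for the oxidative phosphorylation, 0.135 for the neuronal and 0.135 for the sterol list. The smallest p this design allows is 0.00794, and after adjustment over 35 lists the smallest exact p was 0.833. Even at that smallest possible p, a single list could not pass after adjustment, so the adjusted exact test cannot decide on single lists. No list passed in fry, whose smallest adjusted p was 0.944 for a shift one way and 0.561 for changes either way.

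**Figure D2:**
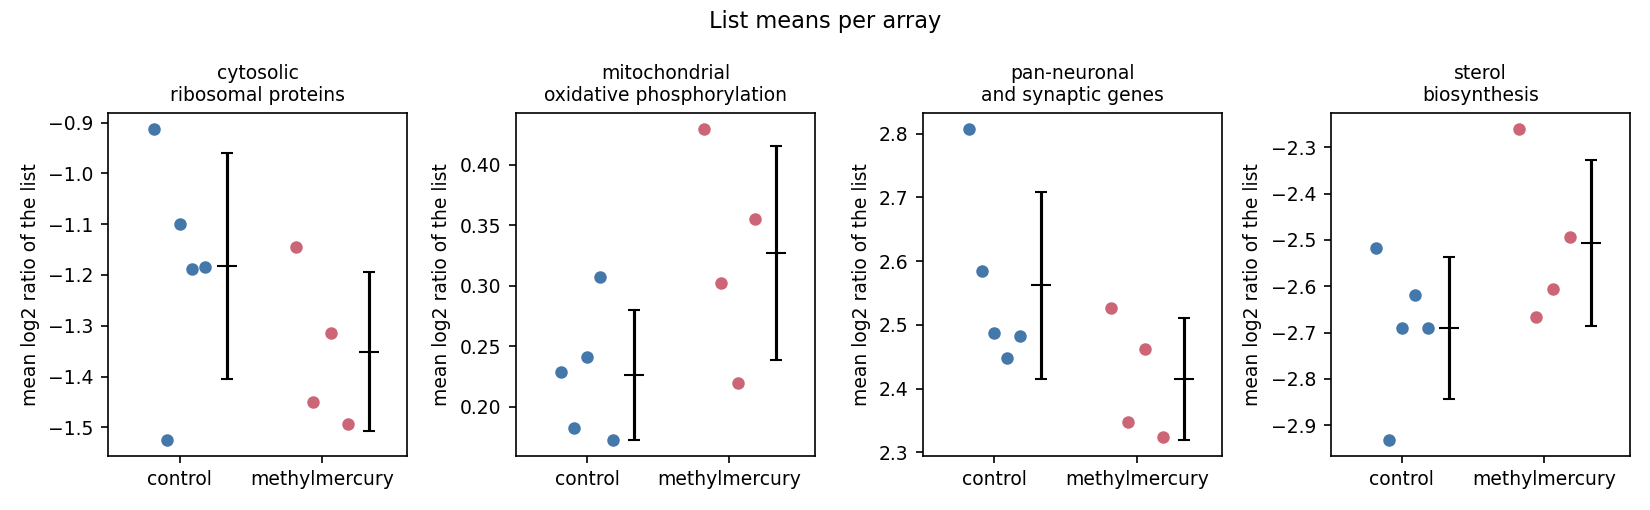
Mean log2 ratio of sample over reference for 4 gene lists in each of the 5 control (blue) and 4 methylmercury (red) pools, with the group mean and SD as a black bar. The ribosomal means are -1.18 and -1.35, and under median centring the median differences of the ribosomal and neuronal lists turned to 0.14 and 0.03.

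In the lists, the count of changed genes over all probes was 0 in limma, and adjusted over the list alone a single gene passed in each of 5 lists. These were gsta.1 among 22 glutathione and Nrf2 target genes, ndufb2 in oxidative phosphorylation, gria1a among 12 glutamate signalling genes, ndrg2 among 21 astroglia and radial glia markers and cirbpb among 11 hypoxia and cold-shock genes. In the other lists 0 genes passed. Single pools weigh on the values below, since with 1 array left out 81 of 128 further leading members of lists moved by over 1.5 times at least once.

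Stress and metal response lists did not pass in camera in the reported setting, with adjusted p between 0.165 and 0.814. With median centring the glutathione and Nrf2, thiol redox enzyme, glycolysis and cell death lists passed. The redox enzyme list also passed with the replicate block and without control 5, and the cell death list without methylmercury 2. Without control 1 and methylmercury 1 the hypoxia and cold-shock list passed. The glutathione and Nrf2 list, the main defence against thiol-reactive compounds, had 14 positive and 8 negative genes and a median of 0.07, with gsto1 at 0.29 and gpx4b, a lipid peroxide reductase, at 1.31 with a standard error of 0.69, after gsta.1. Superoxide, peroxide and thiol redox enzymes had 15 positive of 19 genes and a median of 0.12, with sod2, the mitochondrial superoxide dismutase, at 0.37 and prdx2, a peroxiredoxin abundant in red cells, at -0.35. Metallothionein and metal handling genes had a median of 0.01 over 9 genes, with a negative sign in 4 of 6 other scalings, and were led by cp, the copper carrier ceruloplasmin, at -0.70 and fth1a, a ferritin, at -0.25. Heat shock chaperones had a median of 0.01 over 22 genes, with a negative sign in 3 of 6 other scalings, and included bag3, a cochaperone, at -0.17 and hspe1, a mitochondrial chaperonin, at 0.26. Endoplasmic reticulum stress genes had a median of 0.05 over 17 genes, negative in the series value table, with the chaperones hsp90b1 at 0.60 and dnajb11 at 0.35. Proteasome genes had a median of 0.04 over 35, negative in 2 of 6 other scalings, with the subunit genes psmd13 at 0.23 and psmd4a at -0.39. Hypoxia and cold-shock genes had a median of 0.02, with vegfaa, a vascular growth factor, at 0.23 beside cirbpb at 0.69. For cell death and p53 target genes, 16 of 20 were positive and the median was 0.09, with gadd45ga at 0.26 and baxa, a pore-forming death factor, at 0.20. Glycolysis genes had a median of 0.04 over 23 genes, with ldha, a lactate dehydrogenase, at 0.29 and slc2a3a, a glucose transporter, at 0.30.

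Signalling and neuroendocrine lists also did not pass in camera in the reported setting, with adjusted p between 0.165 and 0.992. The nuclear factor kappa B list passed with the replicate block and without control 5. Immediate early genes had 10 positive and 10 negative members and a median of 0.00, negative in 5 of 6 other scalings, with the transcription factor klf2a at 0.29 beside fosab at -0.60. Clock genes were split 10 to 10 with a median that changed sign in 3 of 6 other scalings, with bmal1a, an activator of the clock, at 0.36 and cry2, one of its repressors, at -0.47. Glucocorticoid response genes had a median of 0.05 over 15 genes, with mt2 at 0.12 and the receptor gene nr3c1 at -0.13. Steroid synthesis genes had 11 positive of 12 and a median of 0.09, with sult2st1, a sulfotransferase, at 0.36 and pgrmc2, a progesterone-binding membrane protein, at 0.11. Hypothalamic peptides had a median of -0.03 over 11 genes, positive in 2 of 6 other scalings, with pnocb at 0.28, scg2b, a granin, at -0.10 and oxt, the oxytocin-type peptide gene, at -0.73 with a standard error of 0.56, which was -0.26 without methylmercury 4. Inflammation genes of the nuclear factor kappa B list had a median of 0.14 over 10 genes, with irf1b at -0.44, which was -0.14 without control 5, and nfkb2, a subunit of the factor, at 0.13. Interferon response genes had a median of 0.04 over 9, negative in 2 of 6 other scalings, with stat1a at -0.11 and trim25 at 0.09. Complement genes had a median of 0.03 over 8, negative in 3 of 6 other scalings, with fga, a fibrinogen chain, at -0.63, which was -0.22 without control 1, and c7b at 0.11. Glutamate signalling genes had a median of -0.01 over 12, positive in 6 of 6 other scalings, with gria2b, a second AMPA receptor subunit, at -0.47 and the glial glutamate transporter gene slc1a3a at 0.40. GABA and glycine genes had a median of -0.04 over 18, positive in 3 of 6 other scalings, with the glycine receptor gene glrbb at 0.19 and the transporter gene slc6a22.1 at 0.17. Dopamine, serotonin and acetylcholine genes had one of 0.05 over 8, with ddc, which makes dopamine and serotonin, at 0.24 and mao, which degrades them, at 0.23. The pituitary hormone list had fewer than 5 measured genes.

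Cell type lists gave the following medians, none past the threshold in camera in the reported setting, with adjusted p between 0.420 and 0.885. The microglia, macrophage and leukocyte list passed with median centring, with the replicate block and without control 5. The photoreceptor list passed without control 2 and without methylmercury 2, and the oligodendrocyte list without methylmercury 4. Astroglia and radial glia markers had 0.05 over 21 genes, with ndrg2 at -0.48, id3, an inhibitor of differentiation, at 0.61 and the adhesion gene cdh2 at -0.37. Oligodendrocyte and myelin markers had 0.09 over 13 genes, with cldnk, a myelin claudin, at 0.39, the tetraspanin gene cd9b at 0.44 and plp1b, a main myelin protein, at 0.48. Microglia, macrophage and leukocyte markers had 0.07 over 29 genes, with the lysosomal protease gene ctsd at 0.44 and nccrp1, a receptor of cytotoxic cells, at 0.44. Endothelial and pericyte markers had 0.09 over 13 genes, with kdr, a receptor of vascular growth factor, at 0.38 and cavin2b, a caveola coat protein, at 0.36. Cell proliferation genes had 0.03 over 25 genes, with rrm2l, a ribonucleotide reductase, at 0.29 and fen1, a DNA repair nuclease, at 0.12. Tubulins had 0.03 over 8 genes, with tuba1b at -0.30 and tuba8l3 at 0.17. Cytoskeleton and axon growth genes had 0.01 over 21, negative in 3 of 6 other scalings, with marcksl1b, an actin regulator of growing neurites, at -0.37 and cfl2, a cofilin, at 0.21. Erythrocyte markers had 0.14 over 17 genes, with prdx2 at -0.35 and znfl2a at -0.24. Skeletal muscle markers had 0.02 over 24 genes, negative in 4 of 6 other scalings, with tnni2a.2, a troponin, at -0.16 and actn3a, an actinin, at 0.18. Liver-secreted, skin and meninges genes had -0.01 over 24, positive with median centring, with the egg yolk gene vtg3 at -0.75 and the keratin gene krt5 at 0.74, which was 0.23 without methylmercury 2. The photoreceptor list had a median of 0.18 over 28 genes, with gnb1b, a G protein subunit, at -0.50 and otx2b at 0.22, but its array means lay in separate clusters within each group.

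Photoreceptor and pineal transcripts were present in some pools of both groups, a pattern chosen after the values were seen. The opsin gene exorh, expressed in the pineal organ, was well above background in control 2 and control 3 and in methylmercury 1, methylmercury 3 and methylmercury 4, at log2 ratios between 1.66 and 2.04, and between -0.56 and -0.36 in the other pools. The phototransduction genes gngt1, a transducin subunit, and pde6c, a phosphodiesterase subunit, were well above background on the same 5 arrays. Ratios of gngt1 lay between 2.04 and 2.32 there and between -0.59 and -0.46 elsewhere. Mean ratios of the photoreceptor list were 0.97 and 0.86 in control 2 and control 3, 0.05, 0.08 and 0.05 in control 1, control 4 and control 5, and 0.99, 0.07, 0.84 and 0.92 in methylmercury 1 to 4. In an exact two-sided permutation test of the list means between the groups, p was 0.357.

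Single pools also differed in other genes, again chosen after the values were seen. In control 1, the 3 probes of oaz1a, which encodes an antizyme that limits polyamine synthesis, had log2 ratios of -6.23, -3.69 and -5.77, against values between 0.69 and 2.13, between -0.59 and 0.83 and between 0.87 and 2.47 in the other 8 pools, and only 1 of the 3 was well above background there. The globin gene hbba1 had a ratio of -3.49 in control 1, against -0.52 to 2.17 elsewhere. In control 5, both probes of irf1b, an interferon-responsive transcription factor, had ratios of -1.29 and -1.24, against at most -2.59 and -2.38 in the other pools.

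**Figure D3:**
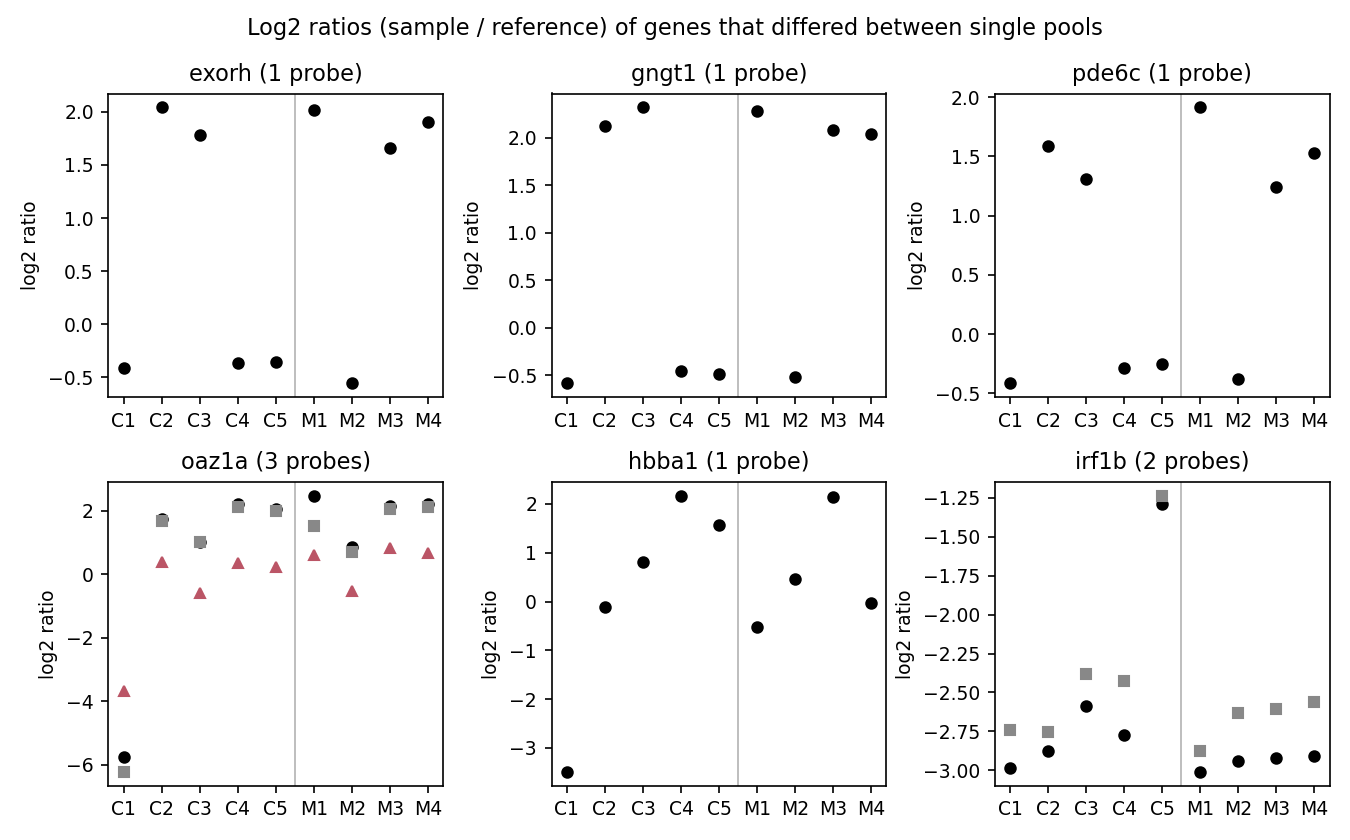
Log2 ratios of sample over reference for 6 genes on the arrays of control pools C1 to C5 and methylmercury pools M1 to M4, where each marker shape is a probe. The photoreceptor genes exorh, gngt1 and pde6c are high in C2, C3, M1, M3 and M4, oaz1a and hbba1 are low in C1, and irf1b is high in C5.

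Arrays differed in quality. On the array of methylmercury 1, spot position accounted for 34.5% of the variance of the deviations from each probe's median, against 1.97% to 10.1% on the others, and neighbouring spots correlated at 0.56, across spots, against 0.04 to 0.21. The first principal component, with 28.3% of the variance, set control 1 apart, and the next, with 21.4%, set methylmercury 1 apart. Without both arrays, an alternative added after the data were seen, 1 probe changed, again TC294381, and 5 lists passed camera.

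**Figure D4:**
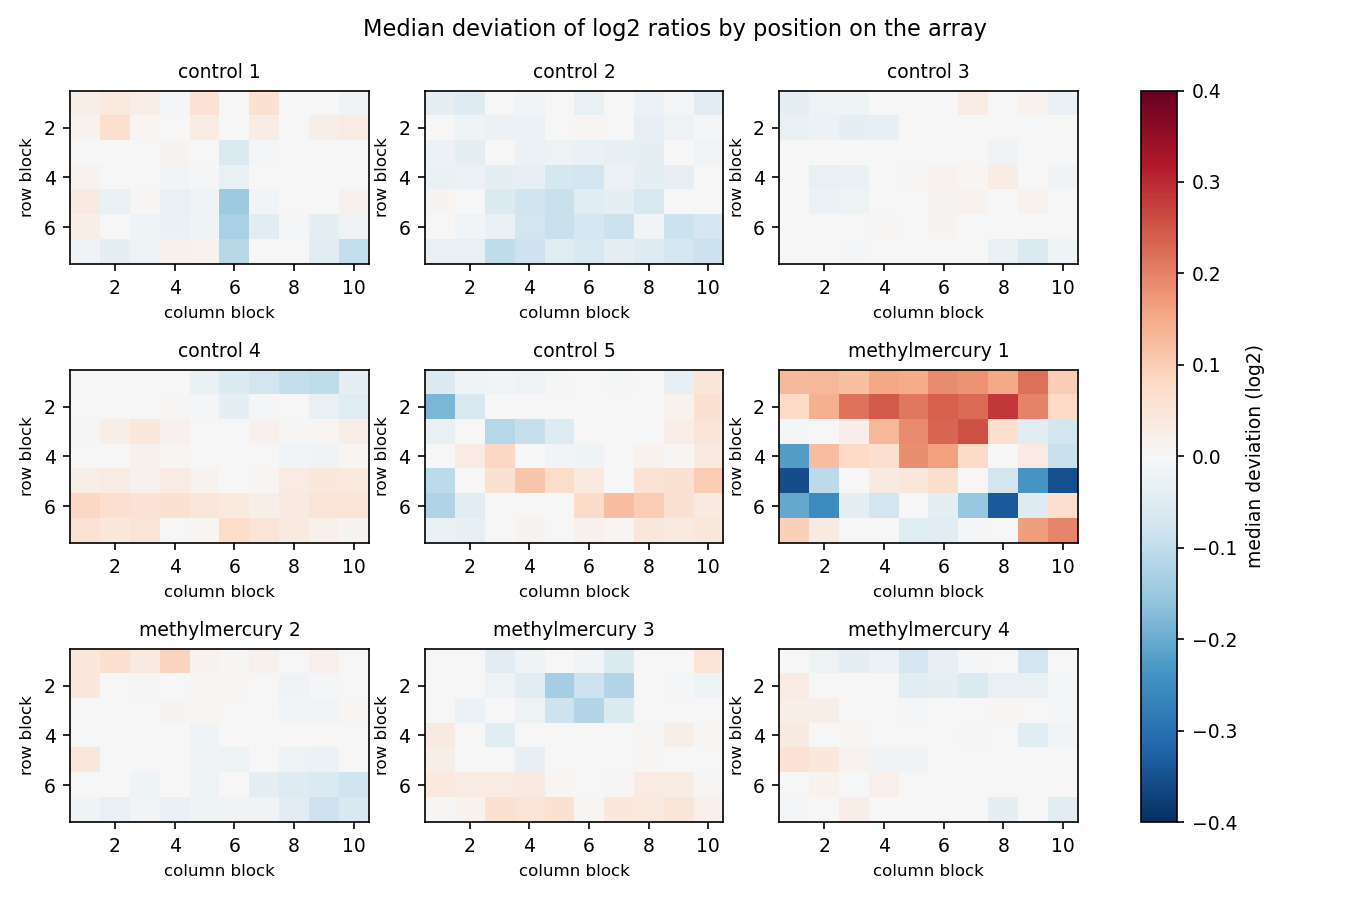
Median deviation of the log2 ratio from each probe's median over the 9 arrays, in a grid of 70 blocks of spot rows and columns, 1 panel per array, on a colour scale in log2 units. Block medians run from -0.35 to 0.28 on the array of methylmercury 1, where red and blue regions are visible.

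The reference channel differed from the brain samples in its tissue transcripts. Averaged over the 9 arrays, liver genes were far lower in the brain samples than in the reference, with log2 ratios of -7.01 ± 0.60 (SD, n = 9) for serpina1, a protease inhibitor secreted by liver, and -6.97 ± 0.33 (SD, n = 9) for fgg, a fibrinogen chain, each on its lowest probe. The other probe of serpina1 gave -5.61, and those of fgg -5.50 and -4.69. Digestive enzyme genes of the pancreas were as low, with -6.73 ± 0.62 (SD, n = 9) for cela1.6, an elastase whose other probe gave -3.54, and -5.90 ± 0.31 (SD, n = 9) for amy2a, an amylase whose other probe gave -6.05. Skin keratin krt4 had -5.68 ± 0.23 (SD, n = 9) and -3.31 on its 2 probes well above background in both channels on every array, and -2.50 to -0.29 on 4 probes that were not so in the sample channel. Brain genes lay on the other side, with 3.61 ± 0.21 (SD, n = 9) for gpm6ab, a neuronal membrane glycoprotein, and 3.49 ± 0.23 (SD, n = 9) for glula, the glutamine synthetase of glia, whose other probe gave 1.48. By list, the median log2 ratio was 2.50 for pan-neuronal genes, 1.06 for astroglia and 1.01 for myelin markers, against -2.55 for liver-secreted, skin and meninges genes, -2.98 for complement genes and -0.81 for skeletal muscle. These genes were chosen after their values were seen.

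**Figure D5:**
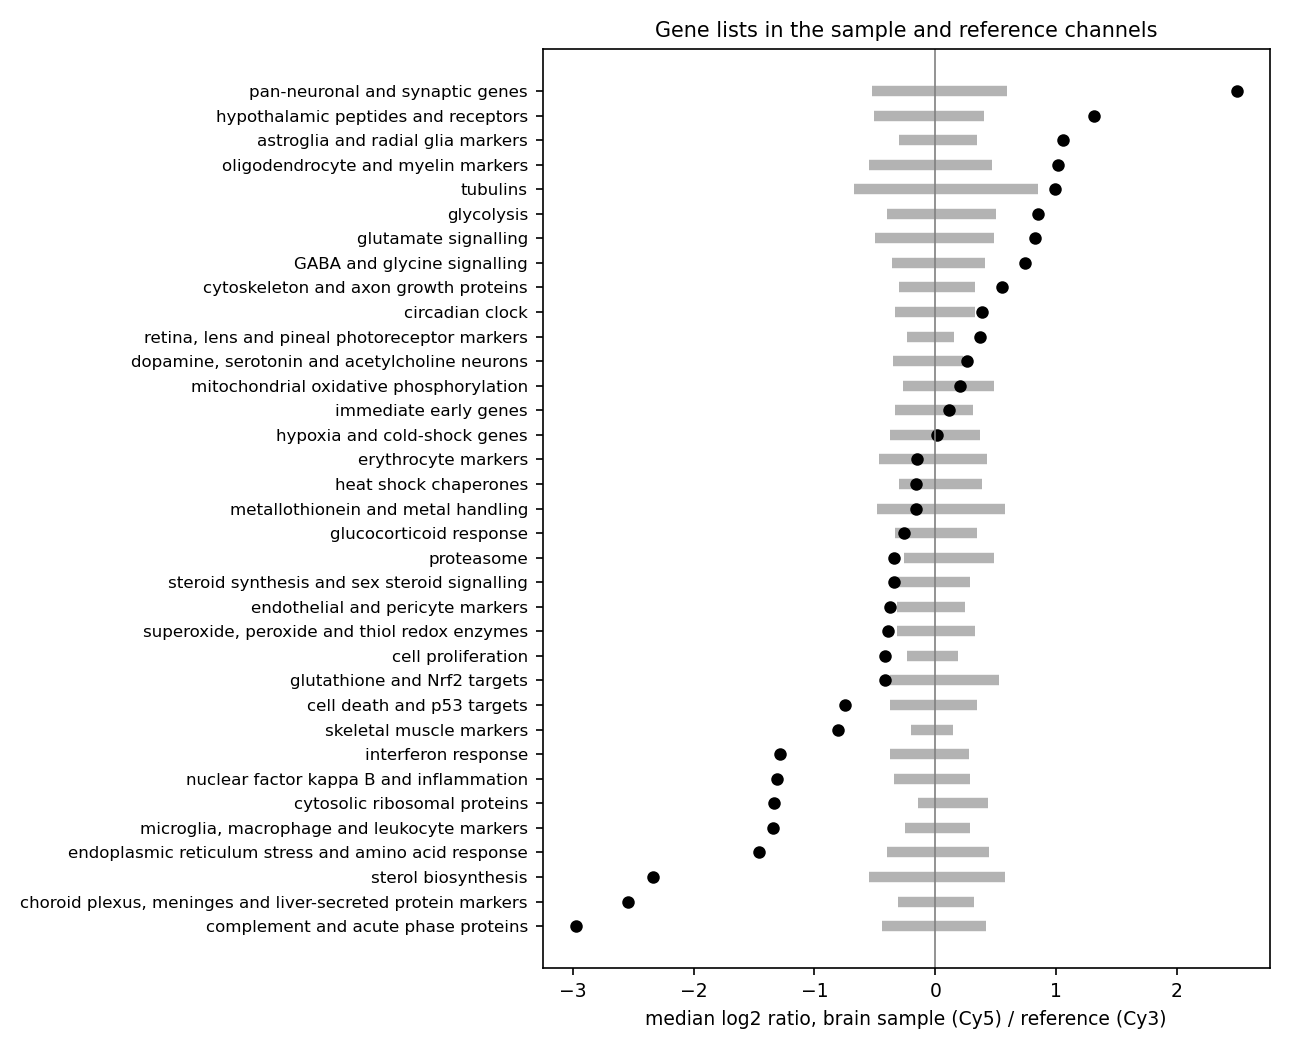
Median log2 ratio of brain sample over reference, averaged over the 9 arrays, for each of 35 gene lists (black points), with the central 95% of medians of 2000 random lists of the same size and brightness (grey bars). Pan-neuronal genes lie at 2.50 and complement genes at -2.98.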

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

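The tests on the reference channel, on the photoreceptor genes and on the sample and reference signal of oaz1a were chosen after the results had been seen, while the counts over other splits were set before. The test of spots beside oaz1a was set before its own result, but oaz1a itself was picked after its values were seen.

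Other splits of the 9 arrays into 5 and 4 were drawn, 100 of the 126 possible. At least 1 changed probe was found in 15 of the 100 splits, the real one included, against a real count of 1 and a highest other count of 27, so chance cannot be excluded. At least 123 probes with an unadjusted p below 0.01 were found in 13 splits, with a highest other count of 311, and at least 4 lists past the camera threshold in 65 splits, with a highest other count of 12, so chance cannot be excluded for either. Over the other splits the median was 66 such probes and 5 lists. The ribosomal list had a camera p as small as the real one in 29 splits, the real one included. The split with 27 changed probes set control 1, control 4, control 5 and methylmercury 2, in which exorh was not well above background, against the other pools. That split had 67 probes at unadjusted p below 0.01 and 2 lists, both below the real 123 and 4. It crosses the treatment groups. Which transcripts the 27 were was not examined, so the count does not show what set these pools apart.

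In the reference channel, which the comparison of groups uses as a denominator, 1065 probes were well above background on all 9 arrays while the sample channel was on none, and 48 probes showed the opposite. Dye bias of single probes is argued against, since 0 of 2000 random lists of matched brightness had a median ratio as low as the -2.55 of the liver-secreted, skin and meninges list. Channels exchanged in the files are argued against too, since the lowest array still had a median of 2.26 for pan-neuronal genes. The liver-secreted, skin and meninges list lay at -5.04 relative to the pan-neuronal list, which is consistent with RNA of other tissues in the reference as a candidate explanation, whereas the labels describe a brain pool. No biological explanation was tested, as the design has no group that differs in its reference.

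Photoreceptor genes were present in some pools and near background in others, and of 11 probes of the list well above background on as many arrays as exorh, 10 shared its pattern over the 9 arrays, against 10 of 328 other probes (Fisher's exact test, two-sided, p = 4.09e-13). The pattern itself prompted this test and the probes are not independent, so the p only describes the overlap. Of 11 cone opsin probes, 0 followed the pattern of exorh and 8 were never well above background. Of the rest, a probe of opn1mw4 was well above background on all 9 arrays, at log2 ratios of 0.52 to 1.25, and 2 probes of opn1lw1 on 3 arrays. The opsins argue against retinal tissue with its cones only as far as their probes can detect it, which was not shown for those 8. The photoreceptor list covers retina as well as pineal organ, and its members gnat2 and pde6c did follow the pattern, so the list itself does not separate these tissues. No rod opsin was found among the array's names, and rods are left open. Methylmercury as the whole cause is argued against by the 2 control arrays with exorh, and an effect of treatment on top of it remains untested. Pineal tissue taken along in some pools is a candidate explanation that these 10 probes, among them crx, rbp3, gnat2 and pde6a, would fit. Of the 83 probes of the list, 12 were well above background on all 9 arrays and so could not share the detection pattern. Among these 12, rpe65a still had log2 ratios of 1.97 to 2.78 in the pools with exorh and -0.35 to 0.48 in the others. The rest of the 12 did not separate the pools in this way. The mean of this list was also an outlier within the methylmercury group, where methylmercury 2 had 0.07 and the others at least 0.84 (gap over range 0.840).

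The transcript oaz1a was near background in control 1 alone, with Cy5 intensities of 18.8, 26.2 and 53.4 for its 3 probes, against at least 4704, 580 and 4901 on the other arrays. A local artifact is argued against, since the 3 spots lie in distant rows, 92, 2 and 78, none was flagged, and 7 neighbouring probes had a median deviation of 0. Loss of signal across the sample is argued against, since 0.181% of the probes of control 1 lay more than 2 log2 units below their median, and a change on the reference side by Cy3 deviations no larger than -0.18. The paralogue oaz1b had a ratio of 1.94 there, against 1.49 to 1.92 elsewhere. No biological explanation was tested, since the labels give all pools the same strain and genotype, and a difference between fish in this transcript would have to be shared by both pooled brains.

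By Dixon's test, values lay apart from the rest of their group in 6 of 142 groups examined, where chance gives about 7.1. The photoreceptor list above is among them, and the others follow. For park7, methylmercury 4 had a log2 ratio of 0.42 and the next pool 0.04 (gap over range 0.896). For mbp, methylmercury 3 had 1.77 and the next 0.45 (0.874). Control 2 had -0.81 for rpl7, with the next at -0.24 (0.796), and also the lowest mean of the endoplasmic reticulum stress list, -1.80 against -1.67 (0.730), and of the cell proliferation list, -0.54 against -0.37 (0.732).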

How the results depend on the processing

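The removal of the position trend and the omission of the arrays that stand apart were chosen after the result was seen, and all other alternatives were set before the data were examined. The changed probe TC294381 was called in 20 of 23 alternatives, with log2 differences of 0.89 to 1.33. The number of changed probes was 0 with processed signals (58 at unadjusted p below 0.01, 25 higher and 33 lower, and 1 list) and 0 with median centring (30 at that p, 29 higher and 1 lower, and 7 lists, all higher). It was 2 with an offset of 10, with array weights, with the position trend removed and with Cy5 alone, which also gave 2 lists. Of these added calls, tp53bp2a passed with the offset of 10, array weights (0.93) and the position trend removed (1.00 with a standard error of 0.10, against 1.05 and 0.14), and cirbpb passed with Cy5 alone (0.65, adjusted p 0.0285, range 0.0285 to 0.998). With no filter on dim probes, 224 of 21495 probes had an unadjusted p below 0.01. The number of lists was 2 with trended robust variances and with the series table, and 0 with an estimated correlation and with fry. Values that reversed were the ribosomal list (0.14) and txnrd3 (0.12) with median centring, and gfap (-0.0183) without both arrays that stand apart. The median of the neuronal list also turned to 0.03 with median centring, while its direction in camera stayed negative. The cause was not tested for any of these.

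Leaving out each array in turn gave 1 to 2 changed probes, 99 to 180 at unadjusted p below 0.01 and 2 to 7 lists. There were 2 changed probes without control 5, where kdm7aa was added (-1.28), and without methylmercury 2, where a probe named TC268571 was added. Without methylmercury 3 the count at unadjusted p below 0.01 was 180, without methylmercury 3 or 4 the lists numbered 2, and without control 5 they numbered 7. Over 26 settings other than the reported one, the ribosomal list passed in 21, oxidative phosphorylation in 23, the neuronal list in 13 and sterol biosynthesis in 12. Oxidative phosphorylation was lost without methylmercury 4 (adjusted p 0.0514, range 4.86e-05 to 0.944). Of 870 values of single genes, 860 kept their direction and their side of the threshold, 3 lost a call, 5 gained one and 2 reversed, where a sign change of an uncalled value by less than its standard error counts as kept. Only TC294381 was called in the reported setting, and many of the other probes were chosen from these same arrays for a small p. The tally therefore says little on stability. With 1 array left out, 5 of the 13 genes chosen in advance changed sign at least once. Of 104 list values, judged by the direction in camera, 69 were kept, 34 lost the call and 1 reversed. Quantile scaling of the mean intensities leaves log ratios unchanged and is left out of these tallies. The median log2 difference of all tested probes was 0.015 in the reported setting and largest with median centring, at 0.089.

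Deviations of equally numbered pools correlated at 0.04, -0.01, -0.08 and 0.26 across probes, and 1 array correlated best with its own number. These values show no general pairing by replicate number, but so few cannot exclude one. In both groups replicate 2 had the brightest sample channel, with median net intensities of 32.0 in control and 22.2 in methylmercury. With the replicate block over the 8 arrays that share a number, 0 probes changed in limma, 118 had an unadjusted p below 0.01, and 7 lists passed. A slide or scan batch was not run. In the dimmest sample channel 40.7% of probes were well above background, and transcripts below that level are not covered.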

Other observations

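The genes here were chosen after their values were seen, and they are given as values of single pools. In control 1, some probes of liver-secreted proteins lay above those of the other pools, although the mean of the liver-secreted, skin and meninges list, -3.36, lay within their range of -3.58 to -3.03. The log2 ratio was -2.50 for fgg on its probe A_15_P107501 against -6.22 to -5.61 elsewhere, and -3.00 on A_15_P117178 against -5.28 to -4.26, while its remaining probe had -7.09 against -7.33 to -6.33. For fga the ratio was -2.97 on A_15_P104121 against -5.41 to -4.77, and -6.02 on its other probe, within the range of the other pools. For ambp and fgb, 1 probe each lay above the other pools and the remaining ones did not, while both probes of serpina1 were highest there, at -4.86 against at most -5.35 and at -6.04 against at most -6.10. In the same pool fkbp5, a chaperone of the glucocorticoid receptor induced by cortisol, had 1.47 against -1.71 to 0.28, while the mean of the glucocorticoid response list, 0.29, lay within the range of -0.21 to 0.30 of the other pools. Red cell transcripts were lowest there, with -3.36 for the globin gene hbaa1 against -0.99 to 0.73 and -2.02 for slc4a1a, the red cell anion exchanger, against -1.21 to -0.23. The mean of the erythrocyte list was -0.90 in control 1 and -0.27 to 0.54 in the others.

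Control 5 had high values of genes induced by interferon and cytokines. The guanylate-binding protein gene gbp1 had a log2 ratio of -0.89 there, against -2.78 to -2.05 elsewhere, with 5 arrays well above background, and socs3b, a feedback inhibitor of cytokine signalling, had -0.93 against -2.46 to -1.73. The macrophage-associated gene mfap4.1 had 0.43 on the probe well above background on 7 arrays, against -1.36 to -0.94. Yet stat1a, a core interferon-responsive transcription factor, had 0.13, within the range of -0.25 to 0.18 of the others. The mean of the interferon list was -0.86 in control 5 and -1.64 to -1.21 in the other pools. The list of microglia, macrophage and leukocyte markers was also highest there, at -1.23 against -1.82 to -1.36, and the leukocyte genes lcp1 and fermt3b lay 1.03 and 1.09 above their medians. Lists without a tie to immunity were highest there too, among them liver-secreted, skin and meninges genes at -3.03 against at most -3.19, metallothionein and metal handling at -1.08 against at most -1.31 and glutathione and Nrf2 targets at -0.45 against at most -0.54. By small margins the redox enzyme and proteasome lists were also highest there, and the collagen gene col1a1b lay 1.00 above its median. Of probes more than 1 log2 unit from their median on a single array and within 0.5 on all others, control 5 had 8, all higher, against 29 in control 1, 15 of them higher, 22 in methylmercury 1, 4 of them higher, and 8 in methylmercury 3, 2 of them higher.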
